A study of Mus musculus with 6 samples.

How the data were processed

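Gene expression was measured on 6 mouse 2-colour oligonucleotide arrays. Each array carried amplified RNA from 1 induced pluripotent stem (iPS) cell line in one dye and RNA pooled from embryonic stem (ES) cells in the other. The 3 lines, iPS1, iPS4 and iPS5, each had 2 arrays of opposite dye orientation, and the labels do not say whether these 2 arrays had separate RNA, so a line counted as 1 replicate. The ES pool was the only control RNA and counted as 1 sample. A ratio tested against 0 therefore leaves out the spread that separate ES cultures would have had.

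The raw scanner files were deposited as intensity per spot and channel, with signal and local background and with no normalization. The dye of each channel was read from the labels and checked on the values: the correlation of the raw channel ratio with the deposited ratios changed sign with the dye orientation. The authors' processed values were deposited as 1 log2 ratio per spot and array and were checked to run as iPS over ES on all arrays; how they were normalized is not stated. The authors' final table gave, per the file headers, a mean log2 ratio of iPS over ES for each reporter, shifted so that the mean over reporters was 0. The same table held a deposited p-value per reporter, in steps of 0.0002, from a test that is not stated.

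All fits started from the raw intensities. Each array held 45220 spots, of which 41174 were gene probes and 4046 were controls, in 1 block. Background was corrected with normexp (offset 50) and each array was normalized with a single loess curve in which control spots had no weight, in limma 3.58.1 with statmod 1.5.0 under R 4.3.3. No step between arrays was added, because quantile normalization of the mean intensities leaves the ratios as they were. Ratios were turned to iPS over ES and are given as log2 values. A channel was taken as above background where it exceeded percentile 95 of a dim control reporter with 604 spots per array, and signals over 65000 were taken as saturated. Where 1 channel of a line was not above background on either of its arrays, its level on each array was taken as the higher of its own signal and the lowest signal among probes above background, and the fold is given as a bound ("at least"). Where its own signal was the higher on both arrays, as for Sp5, Xlr5c, Xlr4c and Xlr5e-ps in iPS5, the bound equals the measured fold.

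Of the gene probes, 34186 had 1 gene symbol and 6988 had none. Symbols were matched to the GRCm38.p6 gene table: 30365 probes had a current symbol, 3726 were updated through a synonym, and 95 had a symbol that the table lacked. The table also gave each gene's chromosome and order. These probes stood for 18295 genes, and a gene with several probes was represented by its brightest probe. Probe positions within transcripts were not used, so no value separates transcripts of a transduced vector from those of the gene in the genome.

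For the comparison of the iPS lines with the ES pool, the 2 arrays of a line were averaged, which cancels the dye effect, and limma's moderated test was run on the 3 line means against 0 (two-sided). For single lines, pairs of lines, the F test among the 3 lines and the dye effect, limma was run on all 6 arrays with 1 coefficient per line and a dye term. There the spread comes from the duplicate arrays of a line and may be technical. P-values were adjusted by the Benjamini-Hochberg method over all 41174 probes, and probes with an adjusted p under 0.05 were called. Gene lists were tested with limma's camera, with a preset correlation of 0.01 between genes and also with an estimated correlation, and with fry, adjusted over the 25 lists. Differences between 2 lines beyond 2-fold were tested with limma's treat.

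The groups, tests, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule took the 10 highest and 10 lowest genes among those called with the same sign on all 6 arrays. It also took the 16 transduced genes with Nanog, Zfp42 and Esrrb. From each list it took up to 4 members with the smallest p in the test described. It took the 5 genes with the largest line difference for each line that stood apart as the highest or the lowest in the F test, and the 3 highest and 3 lowest genes of each line. Predicted and unnamed transcripts were passed over. Of the named genes, the text gives those that a comparison needs.

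The design was tested on simulated data with 100 changed probes per effect size among 41174. The test of the 3 lines found 43% of changes of 0.5 on the log2 scale and 85% of changes of 1, and 5 of its 133 calls were of unchanged probes. The simulated ES pool had no spread of its own. These 5 therefore leave out false calls that a deviating pool would give to all lines together. The F test found 0% of changes of 0.5 in 1 line and 59% of changes of 1. With so few changed probes the adjusted threshold is stricter than on the real arrays. There the F test called 8241 probes, of which 1580 differed by at least 1.5-fold. The simulated shares therefore do not give the power of these tests on the real arrays. In simulated lists of 30 genes shifted by 0.3, camera with the preset correlation gave an adjusted p of 4.87e-44, against 0.152 with an estimated correlation.

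The median signal was 97.91 to 160.3 on the arrays of iPS1 and iPS4 and 52.17 to 63.24 on those of iPS5, over a local background of 34 to 37. The number of arrays limits the precision. Alternatives covered background correction, normalization, detection, the unit of replication, the dye term, the authors' values, a fold requirement and leaving out each array or line. Print-tip normalization was not run because the arrays have 1 block, and no scan date or slide batch is given. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 under Python 3.11.15.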

Results

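RNA of 3 mouse iPS cell lines was compared on arrays with RNA pooled from ES cells. The lines, iPS1, iPS4 and iPS5, were colonies expanded from OG2 embryonic fibroblasts, which carry a green fluorescent reporter of Oct4. The fibroblasts had been transduced with retroviruses for 16 genes: the 4 reprogramming factors Oct4, Sox2, Klf4 and c-Myc, and 12 subunits of TFIID, the general transcription factor that binds core promoters. The ES cells carried the same reporter, and both cell types were grown on fibroblast feeder cells with LIF. Each line was measured on 2 arrays of opposite dye, so that 6 arrays stood for 3 lines, and the ES pool was a single sample. The share of gene probes above background was 65.18% to 87.08% per channel on the arrays of iPS1 and iPS4 and 47.44% to 65.69% on those of iPS5.

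The iPS and ES channels of an array were closely alike. Across probes, which are not independent replicates, the normalized log2 intensities of the 2 channels correlated with r = 0.979 to 0.986. In the mean of the lines, 247 of 41174 probes lay beyond 2-fold (807 with a background offset of 0). The log2 ratios of the 2 arrays of a line, whose dyes were opposed, correlated across probes with r = 0.741 for iPS1, 0.766 for iPS4 and 0.656 for iPS5. With the authors' values these were 0.941, 0.949 and 0.819. Arrays of different lines correlated with r = 0.322 to 0.795. The highest, 0.781 and 0.795, joined iPS1 and iPS4 arrays of the same dye orientation and exceeded every pair within a line. The lowest joined iPS1 and iPS5 arrays of opposite orientation. With the authors' values, arrays of different lines correlated with r = 0.506 to 0.773, below every pair within a line. Whether dye orientation outweighed the line thus depended on the processing. The dye term passed limma's threshold for 7631 probes (0 with offset 0, where limma gave 11506 at an unadjusted p under 0.05).

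The first comparison asked how the iPS lines differed from ES cells. Every line came from cells given the reprogramming factors and the TFIID subunits together, so no difference can be tied to the subunits alone. The gene furthest above the ES pool was Ipp, whose name comes from its promotion by an intracisternal A particle, at a log2 ratio of 4.23 ± 0.523 (SD, n = 3 lines; adjusted p = 0.0201). Interferon-inducible genes among the 10 highest were Irgm1 at 2.53 ± 0.134 (adjusted p = 0.0201), Ifi27 at 2.06 ± 0.565 (0.0322), Tgtp2 at 1.77 ± 0.427 (0.029) and Rtp4 at 1.68 ± 0.387 (0.0277). Id1, an inhibitor of differentiation that BMP signals induce, stood at 2.32 ± 0.732 (0.0374), and the imprinted gene Plagl1 at 2.05 ± 0.159 (0.0201). The other 3 of the 10 highest genes were Dync2h1, a motor subunit of cilia, at 1.99 ± 0.569, Wtap, a subunit of the RNA m6A methyltransferase complex, at 1.90 ± 0.177, and Baiap2l1 at 1.78 ± 0.199.

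Among the lowest genes was Zfp42 (Rex1), a marker of naive pluripotent cells, at -2.74 ± 0.383 (adjusted p = 0.0201). Lower still were Rpgrip1, a gene of photoreceptor cilia, at -3.48 ± 0.894 (0.0302), Efhc2 at -2.92 ± 0.882 (0.0354) and Thumpd1 at -2.74 ± 0.986 (0.0433), whose iPS channel was above background on 3 of 6 arrays. Genes induced by stress or low oxygen were also far down: Chac1 at -2.40 ± 0.294 (0.0201), Nupr1 at -2.26 ± 0.558 (0.0296) and Bnip3 at -2.28 ± 0.632 (0.0324). Anxa2 stood at -2.24 ± 0.327 (0.0201), the imprinted growth factor gene Igf2 at -2.12 ± 0.467 (0.026) and Ptgs2, which encodes cyclooxygenase-2, at -2.02 ± 0.747 (0.0445). All 20 of these genes had the same sign on 6 of 6 arrays, as the rule for naming them required. Probes of a gene did not always move together: 2 of 4 were called for Ipp, the others standing at 0.05 and 0.08, 2 of 5 for Rpgrip1, 2 of 3 for Irgm1, Anxa2 and Efhc2, 1 of 2 for Plagl1, Ifi27, Tgtp2 and Thumpd1, 1 of 3 for Wtap and 1 of 9 for Dync2h1.

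**Figure D1:**
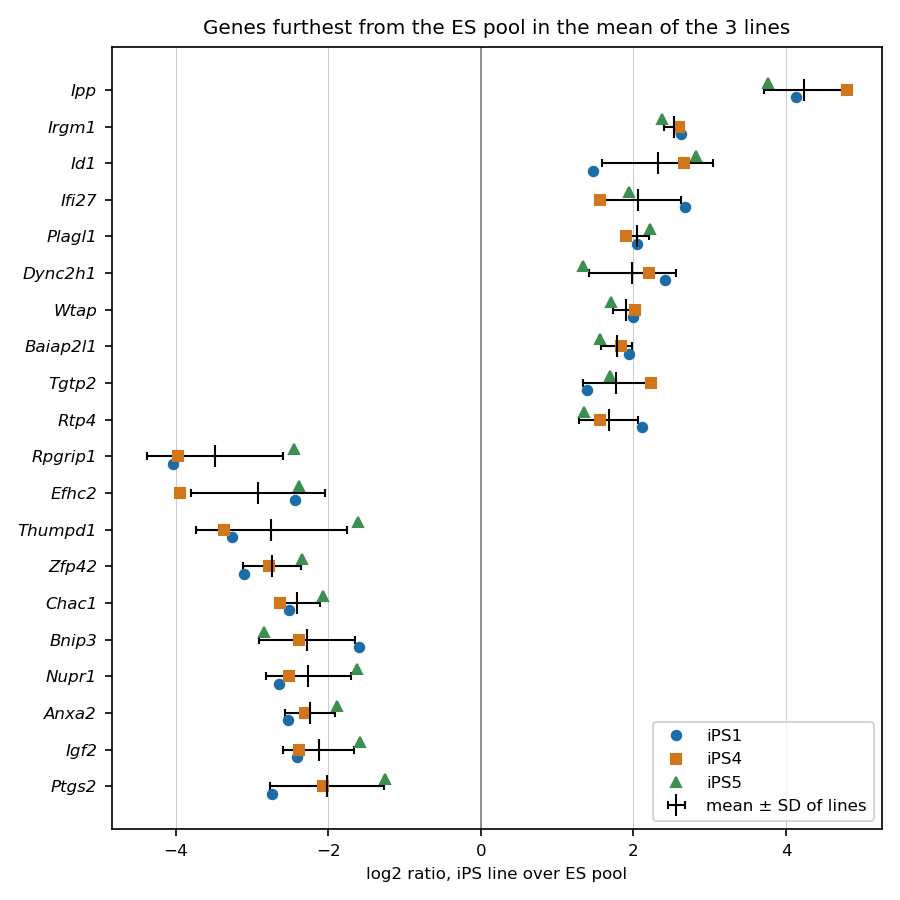
Log2 ratios (horizontal axis) of the 10 highest and 10 lowest genes called with the same sign on all 6 arrays, with 1 symbol per line and the mean ± SD of the 3 lines. Means run from 4.23 for Ipp down to -3.48 for Rpgrip1.

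Across the array, limma called 3161 of 41174 probes, 1590 higher and 1571 lower, and 154 of them lay beyond 2-fold (67 higher, 87 lower). By gene, 1859 of 18295 were called, 953 higher and 906 lower, of which 913 and 882 had the same sign on all 6 arrays. These calls rested on the lines: without iPS1 or without iPS4 limma called 0 probes (8786 and 5960 at an unadjusted p under 0.05), and without iPS5 it called 5422. Leaving out single arrays gave 457 calls (without iPS5 replicate 1), 1112 (iPS4 replicate 1), 1916 (iPS1 replicate 1) and 5881 (iPS5 replicate 2), and 0 calls were left when the ES pool was counted as a sample that varies like a line (limma, 3766 unadjusted). Without iPS1, without iPS4 and with the ES pool so counted, all 20 named genes lost their call, at adjusted p of 0.0629 to 0.126, 0.201 to 0.265 and 0.288 to 0.479. Of the 20, 11 lost it without iPS5 replicate 1 (0.0533 to 0.0813), 4 without iPS4 replicate 1 (0.0506 to 0.0586), 2 without iPS1 replicate 2 (0.0508 to 0.0586) and Id1 without iPS5 (0.0501). Scaling the arrays to a common spread ended the calls of Id1 and Bnip3 (0.0542 to 0.0556), and averaging a gene's probes ended that of Dync2h1 (0.0572). Of 125 genes followed through the alternatives 80 were called against the pool, and all 80 lost the call without iPS1, without iPS4 or with the pool as a sample, and 48 without iPS5 replicate 1. The 3161 calls became 1526 with gene means, 4967 with median centring, 5048 with arrays scaled, 4883 with offset 0 and 5546 with plain background subtraction, and 8763 and 11427 with all 6 arrays fitted, with and without the line as a random block.

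Of the 4 transduced reprogramming factors, only Myc rose in the mean of the lines, by 1.09 ± 0.421 on the log2 scale (n = 3, adjusted p = 0.0482). Pou5f1, the gene of Oct4, stood at 0.13 ± 0.595 (adjusted p = 0.794), Sox2 at -0.11 ± 0.206 (0.512) and Klf4 at 0.24 ± 0.833 (0.722). Myc was at 0.62, 1.45 and 1.19 in iPS1, iPS4 and iPS5, above 0 in 3 of 3 lines, and 2 of its 3 probes were called. Its call was lost without iPS1 replicate 2 (0.0552), iPS4 replicate 1 (0.065) or iPS5 replicate 1 (0.0789), without any 1 of the lines (0.0629 to 0.24), with gene means (0.053) and with arrays scaled (0.0508). Of the pluripotency genes Nanog rose by 0.65 ± 0.131 (0.0264), and Esrrb was at -0.05 ± 0.604 (0.924). The Nanog call was lost without iPS1 (0.0705) or iPS4 (0.205).

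Of the 12 transduced TFIID subunits, Taf7 rose most, by 1.01 ± 0.252 (adjusted p = 0.0304), with 3 of 3 probes called. Taf12 rose by 0.34 ± 0.119 (0.0499). The other 10 were not called: Taf13 was at 0.40, Taf9 at 0.28, Taf4 at 0.23, Taf11 at 0.22, Taf3 and Tbp at 0.20, Taf4b at 0.05 near background, Taf5 at -0.03, Taf10 at -0.13 and Taf6 at -0.19, with adjusted p of 0.0505 to 0.721. A dimmer probe of Taf4 was called, at 0.28 (0.0383). With p adjusted over the list alone, 8 subunits were higher and 2 lower, and the list as a whole was shifted up by a median of 0.21 (camera adjusted p = 0.0253, against 0.833 with an estimated correlation). The call of Taf7 was lost without iPS5 replicate 1 (0.0733) and without iPS1 (0.0692) or iPS4 (0.218). That of Taf12 was lost without iPS1 replicate 1 (0.0782), iPS4 replicate 1 (0.0676) or replicate 2 (0.0521), iPS5 replicate 1 (0.0834) or any 1 line (0.0692 to 0.282), and with arrays scaled (0.0637), offset 0 (0.064) or plain subtraction (0.05).

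**Figure D2:**
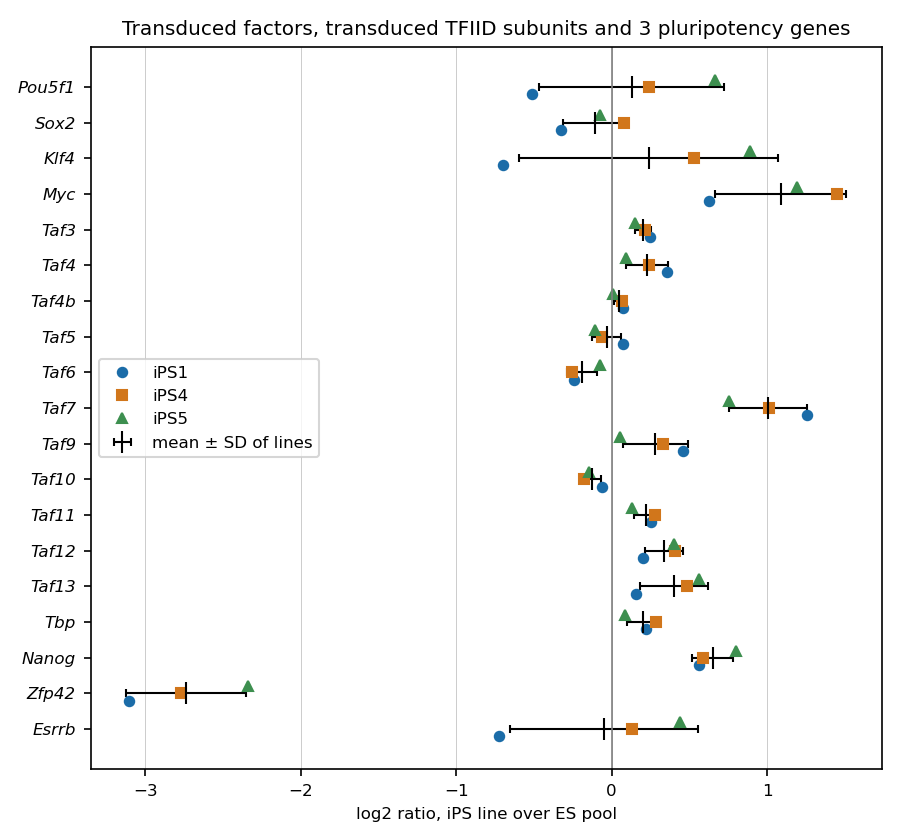
Log2 ratios (horizontal axis) of the transduced factors, the transduced TFIID subunits, Nanog, Zfp42 and Esrrb, with 1 symbol per line and the mean ± SD of the 3 lines. Zfp42 lies at -2.74, while Pou5f1 and Sox2 lie within 1 SD of 0.

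Other parts of the initiation machinery moved both ways. Of 14 other TFIID and TFIID-related subunits, Btaf1 rose by 0.45 ± 0.164 and Taf5l was at -0.23 ± 0.0617, also called; adjusted over the list alone 3 were higher and 3 lower (list median 0.0523, camera adjusted p = 0.635). Of 17 general RNA polymerase II initiation factors, Gtf2f1 and Gtf2b were among 3 called higher, at 0.59 ± 0.184 and 0.33 ± 0.0959. The 2 called lower were Gtf2e2 at -0.54 ± 0.0698 and Mnat1 at -0.36 ± 0.0855. In the list, 6 were higher and 2 lower adjusted over the list alone (median 0.116, camera adjusted p = 0.0725), and that list passed the threshold with median centring (0.0483), gene means (0.0155) and all probes of a gene (0.00507).

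Glycolysis genes were lower in the iPS lines. Of 21 measured, 10 fell and 0 rose, and adjusted over the list alone 15 were lower and 1 higher. The isozyme gene Aldoc stood at -1.28 ± 0.166 (n = 3), the phosphofructokinase genes Pfkp at -1.52 ± 0.313 and Pfkl at -1.08 ± 0.158, and Tpi1 at -1.09 ± 0.245. The list's median was -0.67 (camera adjusted p = 4.59e-05, against 0.833 with an estimated correlation). Cholesterol synthesis genes had a median of -0.34 (camera adjusted p = 0.00325, 0.836 with an estimated correlation). Of 18 measured, 4 fell, among them Cyp51 at -0.66 ± 0.151, Lss at -0.51 ± 0.156 and Mvd at -0.40 ± 0.0431, and 1 rose, Ebp at 0.89 ± 0.262. Adjusted over the list alone 10 were lower and 1 higher, and without iPS5 the list's call was lost (median -0.285, adjusted p = 0.114).

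Stress response genes had a median of -0.37 (camera adjusted p = 0.0024, 0.833 with an estimated correlation). Of 23 measured, 7 fell, among them Chac1, the asparagine synthetase gene Asns at -1.42 ± 0.074 and the transcription factor gene Atf4 at -0.56 ± 0.0261. The heat shock gene Hsph1 was 1 of 2 that rose, by 1.11 ± 0.156. In all, 12 were lower and 3 higher adjusted over the list alone. Fibroblast genes, which mark both the donor and the feeder cells, had a median of -0.38 (3.27e-07, 0.833 with an estimated correlation). Of 37 measured, 5 fell and 0 rose, and adjusted over the list alone 20 were lower and 0 higher. Dcn was at -1.42 ± 0.396, Thy1 at -0.82 ± 0.242, Cdh11 at -0.78 ± 0.23 and S100a4 at -0.32 ± 0.0813.

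Interferon response genes had a median of 0.26 (camera adjusted p = 0.00325, 0.833 with an estimated correlation). Of 27 measured, 5 rose, among them Oas2 at 1.33 ± 0.0703, Ifitm3 at 0.70 ± 0.175 and Irf9 at 0.55 ± 0.138, while Ifitm2 was the 1 that fell, at -0.52 ± 0.165. Adjusted over the list alone 9 were higher and 1 lower. Trophectoderm genes had a median of -0.14 (0.0253, 0.833 with an estimated correlation). Of 16 measured, 5 fell, among them the keratin genes Krt18 at -1.69 ± 0.486, Krt8 at -1.21 ± 0.362 and Krt7 at -0.96 ± 0.241, and adjusted over the list alone 7 were lower and 1 higher. Germ line genes had a median of -0.15 (0.0285, 0.836 with an estimated correlation). The 4 of 28 that fell were Hormad1 at -1.23 ± 0.298, Sycp3 at -0.92 ± 0.363, Tex14 at -0.72 ± 0.196 and Dmrt1 at -0.62 ± 0.227, and adjusted over the list alone 11 were lower and 1 higher. Without iPS5 the germ line call was lost (median -0.161, adjusted p = 0.149). None of the 8 lists that passed camera did so with an estimated correlation, and fry, which asks whether a list moved on balance, gave no adjusted p below 0.155.

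**Figure D3:**
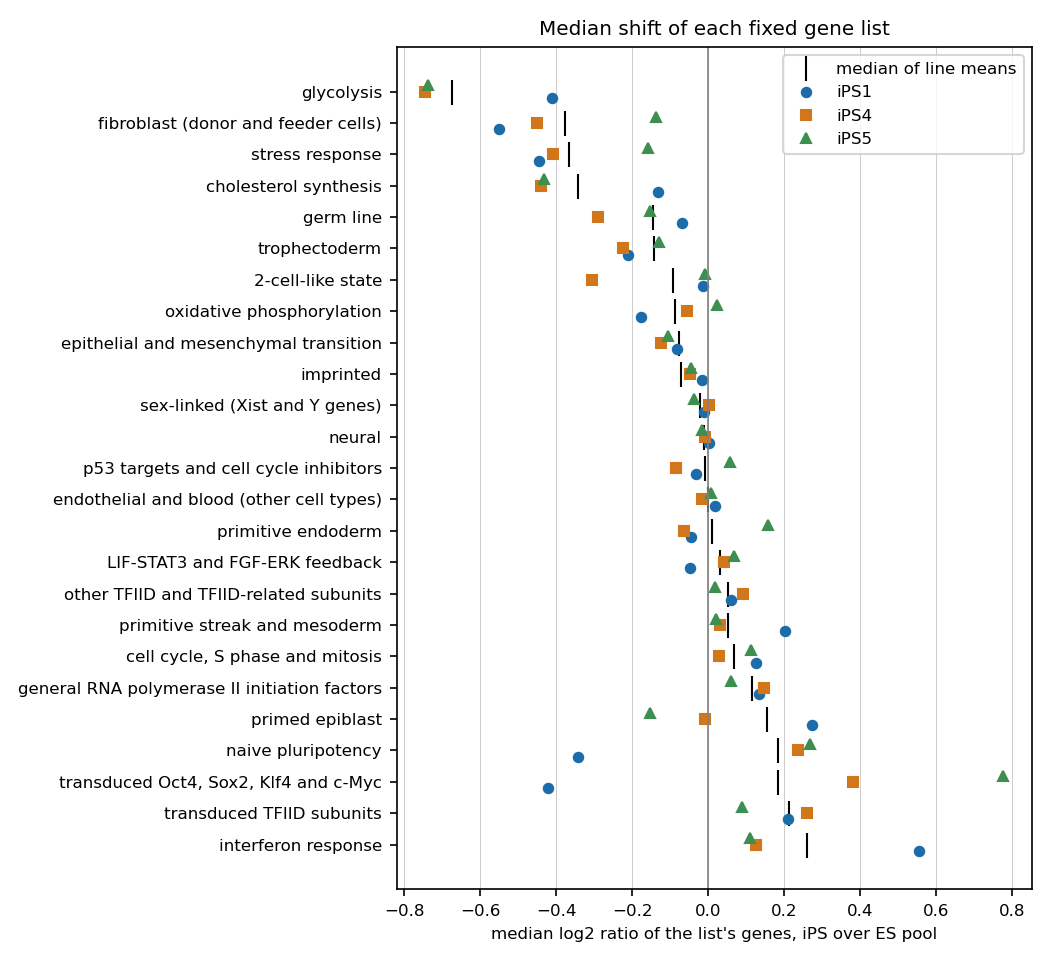
Median log2 ratio (horizontal axis) of the measured members of each gene list, with 1 symbol per line and a bar for the median of the line means. The medians run from -0.67 for glycolysis to 0.26 for the interferon response.

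The naive pluripotency list did not pass the threshold as a whole (31 genes, median 0.18, mean 0.05, camera adjusted p = 0.707), and its median was -0.0868 without iPS5. Its members went both ways: 4 rose, among them Sall4 at 0.65 ± 0.019, and 3 fell, among them Zfp42 and Tdgf1 at -0.38 ± 0.0595. Adjusted over the list alone 7 were higher and 6 lower. Of 18 primed epiblast genes, Zic2 at -0.61 ± 0.0213 and Dnmt3a at -0.56 ± 0.0213 fell and 0 rose (0 higher and 3 lower adjusted over the list alone; median 0.155, 0.868). Of 33 genes of S phase and mitosis, 8 rose, among them Ccne1 at 0.85 ± 0.127, Cenpa at 0.47 ± 0.0812, Cdc6 at 0.34 ± 0.0109 and Aurka at 0.25 ± 0.026, and 1 fell. In all, 13 were higher and 5 lower adjusted over the list alone (median 0.0691, 0.0725), and the list passed the threshold without iPS4 (0.0104) and with median centring (0.0244) or all probes (0.0308). Of 22 genes of LIF-STAT3 and FGF-ERK feedback, the LIF receptor subunit gene Il6st at 0.64 ± 0.122, Socs3 at 0.48 ± 0.0835 and Dusp6 at 0.44 ± 0.0567 rose and Ier3 at -1.54 ± 0.17 fell (3 and 1 adjusted over the list alone; median 0.0313, 0.447).

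Of 29 imprinted genes Plagl1 rose, and 4 fell, among them Igf2, Copg2 at -0.68 ± 0.127 and H19 at -0.66 ± 0.105; adjusted over the list alone 3 were higher and 4 lower (median -0.0714, camera adjusted p = 0.579). Of 23 p53 targets and cell cycle inhibitors, 3 rose, among them Pmaip1 at 0.69 ± 0.16 and Trp53inp1 at 0.62 ± 0.175, and 3 fell, among them Bbc3 at -0.72 ± 0.106 and Cdkn1b at -0.33 ± 0.00977 (3 higher and 5 lower adjusted over the list alone; median -0.00819, 0.706). Of 19 genes of the epithelial and mesenchymal transition the claudin genes Cldn4 at -0.72 ± 0.0502 and Cldn3 at -0.34 ± 0.104 fell (0 higher and 2 lower adjusted over the list alone; median -0.0759, 0.09). Of 24 oxidative phosphorylation genes Cox7a2 rose by 0.35 ± 0.0714 (1 higher and 6 lower adjusted over the list alone; median -0.0869, 0.316). Without iPS1 the transition list passed the threshold (0.0132).

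Among markers of other cell types, limma called 0 of 20 primitive streak and mesoderm genes (4 at an unadjusted p under 0.05; median 0.0524, mean 0.43, camera adjusted p = 0.09), and 0 with adjustment over the list alone. That list passed the threshold without iPS5 (median 0.103, 0.0281) and with subtraction (0.049), median centring (0.0412), offset 0 (0.0395) or all probes (0.0308). Of 21 neural genes Map2 rose by 0.27 ± 0.0554 (1 higher and 1 lower adjusted over the list alone; median -0.0117, mean 0.0257, 0.962). Limma also called 0 of 24 primitive endoderm genes (4 unadjusted; median 0.0107, mean -0.0359, 0.964) and 0 of 19 endothelial and blood genes (5 unadjusted; median -0.00035, 0.962), and likewise 0 adjusted over the list alone. Of 11 measured genes of the 2-cell-like state Eif1a rose by 0.30 ± 0.0908 (1 higher and 0 lower adjusted over the list alone; median -0.093, 0.645). The 4 reprogramming factors as a list had a median of 0.184 (0.581; 1 higher adjusted over the list alone; 0.579 and 0.0196 without iPS1, -0.106 without iPS5), and 8 sex-linked genes had a median of -0.0205 with 0 called by limma either way (1 unadjusted; 0.75). The medians of the neural, primitive endoderm, endothelial and p53 lists changed sign under some processing settings, as did that of the LIF-STAT3 and FGF-ERK list.

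Each line was also set against the ES pool on its own. In iPS1 and iPS4 the mesoderm regulator gene T stood at 3.71 (adjusted p = 9.8e-07) and 3.07 (1.14e-06), and Sp5, a target of Wnt signals, at 3.37 (1.62e-06) and 2.85 (1.6e-06). With Ipp they were the 3 highest genes of both lines. In iPS5 the 3 highest were Ipp at 3.77, Id1 at 2.82 and Coil, which encodes the Cajal body protein coilin, at 2.72, although 1 of the 2 Coil probes differed little. The lowest genes of iPS1 were Rpgrip1, Thumpd1 and Zfp42, at -4.03, -3.26 and -3.10. In iPS4 they were the X-linked lymphocyte-regulated genes Xlr4b at -5.21, Xlr5c at -5.16 and Xlr3c at -4.32. The same 3 genes were the lowest of iPS5, with Xlr4b at -3.72, Xlr3c at -2.95 and Xlr5c at least 9.28-fold lower, its iPS channel not being above background.

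Against the ES pool limma called 14942 probes in iPS1 (7920 higher, 7022 lower), 14939 in iPS4 (7404 and 7535) and 8040 in iPS5 (4185 and 3855), with 469, 501 and 228 beyond 2-fold. These counts measure the spread between duplicate arrays and not between cultures. Without 1 of its own arrays iPS1 had 6684 (replicate 1) and 8413 (replicate 2) calls, and iPS4 had 8429 and 7729. Without a dye term the counts were 8242, 8418 and 2968, and with median centring 7102, 7690 and 2235. Lines shared calls: 5354 probes were higher and 5146 lower in both iPS1 and iPS4, 2809 and 2657 in iPS1 and iPS5, and 3377 and 3214 in iPS4 and iPS5. The numbers called in opposite directions were 428, 634 and 207. Because all lines were measured against the same pool, calls are shared even between unlike lines. The line ratios correlated across probes with r = 0.786 for iPS1 and iPS4, 0.569 for iPS1 and iPS5 and 0.768 for iPS4 and iPS5. Simulations of unchanged lines set against a pool that varies like a line gave 0.498, 0.499 and 0.493. The equal spread assumed for lines and pool fixes these simulated values, and 1 pool cannot check that assumption.

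The lines differed from one another in named groups of genes. A first set was nearest to the ES pool in iPS1 and far below it in iPS4 and iPS5. Xlr4b was at -0.92, -5.21 and -3.72 in iPS1, iPS4 and iPS5 (F test adjusted p = 5.38e-05), Xlr3c at -0.98, -4.32 and -2.95 (1.64e-05), Eif2s3y, a Y-linked gene, at -0.41, -4.23 and -2.91 (2.85e-05) and the securin gene Pttg1 at -0.12, -2.19 and -1.43 (5.56e-05). Xlr5c was at -1.42 and -5.16 in iPS1 and iPS4 (2.24e-05), Xlr4c at -0.77 and -4.14 (0.000274) and the pseudogene Xlr5e-ps at -1.25 and -3.90 (0.000114). The Y-linked Kdm5d, above background on all 6 arrays, stood at -0.04, -0.06 and -0.23. The Eif2s3y and Kdm5d probes thus disagreed, and which of them measures its own gene is unsure. In iPS5 Xlr4c and Xlr5e-ps were at least 3.88-fold and 4.59-fold lower than the ES pool, and in iPS4 they were above background on 1 of 2 arrays.

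A second set stood apart in iPS4. The maternally expressed noncoding RNA Meg3 stood at 0.90 in iPS1, -2.58 in iPS4 and 0.28 in iPS5 (1.34e-05), and another imprinted gene, Grb10, at -0.02, -1.81 and 0.23 (2.09e-05). Genes of the 2-cell-like state were also lowest in iPS4: Zscan4c was at -0.19, -2.88 and -0.66 (1.58e-05) and Zscan4f at 0.69, -1.92 and -0.41 (2.48e-05). Highest in iPS4 were the netrin gene Ntn1 at 0.82, 2.30 and 0.92 (0.000586), Smtnl1 at 0.56, 1.87 and 0.96 (0.000526), Spink1 at -0.02, 1.03 and 0.11 (0.000149), Ipp (0.012) and Pigyl at 0.05, 0.69 and -0.17 (0.00121), although another Pigyl probe stood at -0.32, -0.40 and -0.46. The germ line gene Dazl was at 0.53, -1.51 and -0.37 (9.29e-05).

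Another set was high in iPS1 and iPS4 and lower in iPS5. T stood at 3.71, 3.07 and 0.62 in iPS1, iPS4 and iPS5 (2.96e-05), Fgf5, a marker of the primed epiblast, at 2.71, 1.50 and 0.27 (2.09e-05), Ppp4r4 at 2.71, 1.71 and 0.17 (2.09e-05) and the zinc transporter gene Slc39a8 at 1.16, 2.21 and -0.01 (0.000139). Sp5 in iPS5 was at least 1.49-fold higher than the ES pool, whose channel was not above background there (F test 5.38e-05). The primitive streak gene Gsc was at 2.38 and 0.84 in iPS1 and iPS4, and its highest line was at least 4.13-fold above iPS5, where it was not above background (0.000129). Wnt3 followed at 1.67 and 1.36 (0.000129), with an ES channel not above background on the arrays of iPS5.

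Several naive pluripotency regulators ran the other way, lowest in iPS1 and highest in iPS5. Klf5 stood at -0.39, 0.25 and 1.68 in iPS1, iPS4 and iPS5 (2.09e-05), Nr0b1 at -0.39, 0.62 and 1.51 (4.15e-05), Tbx3 at -0.38, 0.44 and 1.63 (7.63e-05), Klf4 at -0.70, 0.53 and 0.89 (5.14e-05), Esrrb at -0.73, 0.13 and 0.44 (0.000236) and Pou5f1 at -0.51, 0.24 and 0.66 (0.00276). Aard, Lama1 and Apoe had the same order, with -0.51, 0.55 and 1.45 for Aard (9.14e-05), -0.82, 0.18 and 1.02 for Lama1 (0.000101) and -0.77, 0.41 and 1.06 for Apoe (0.000105). Gbx2 was at 0.36, 2.29 and 1.64 (0.00123). Dppa3, also of the naive list, was instead highest in iPS1, at 1.26, 0.94 and -0.86 (2.24e-05). Sox2 was highest in iPS4, at -0.329, 0.0779 and -0.072, and a dimmer Klf5 probe at 0.585, 0.598 and 0.481 lacked the order of the brightest probe. Srgn at -1.47, -2.45 and 0.90 (1.64e-05) and Cubn at -0.83, -1.56 and 1.07 (3.83e-05), both on the primitive endoderm list, and Coil at 0.52, 1.43 and 2.72 (5.86e-05) were highest in iPS5.

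**Figure D4:**
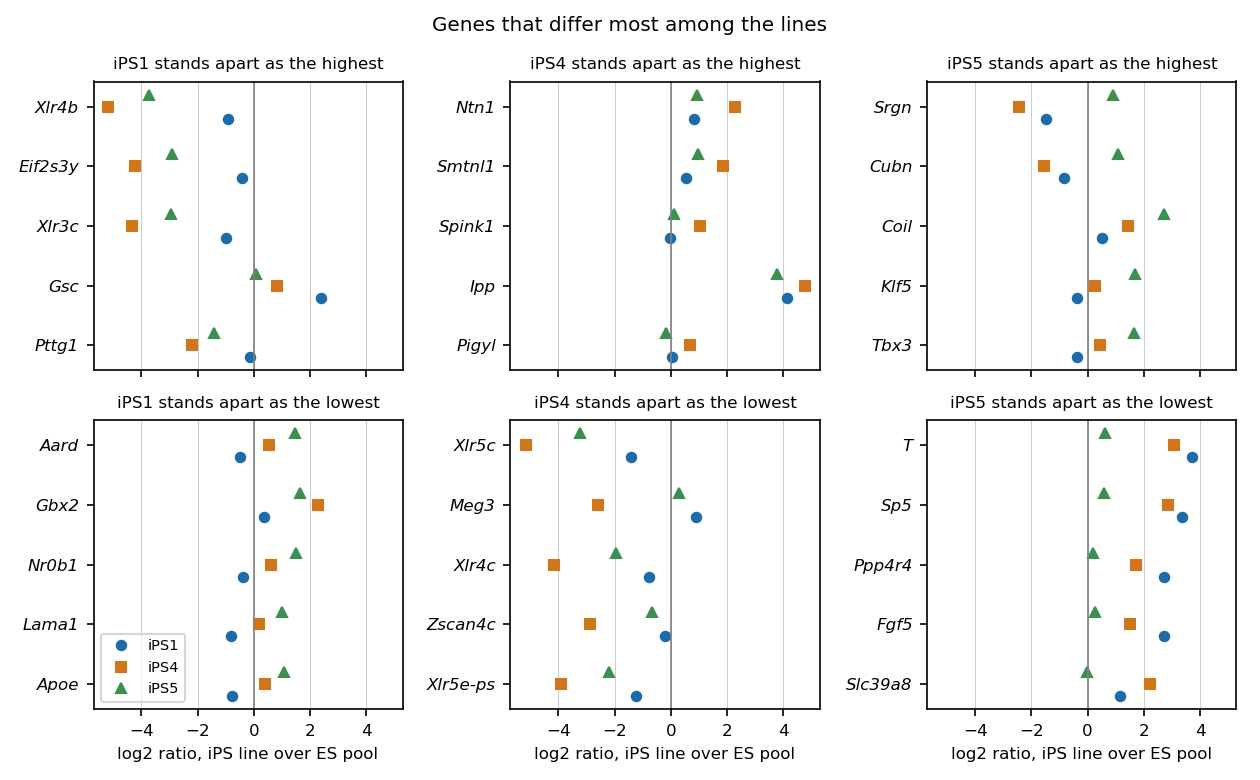
Log2 ratios to the ES pool (horizontal axis) of the genes with the largest line differences, grouped by the line that stands apart, with 1 symbol per line. Xlr4b spans -0.92 to -5.21; the iPS5 symbols of Gsc, Xlr5c, Xlr4c and Xlr5e-ps come from iPS signals, and that of Sp5 from an ES signal, not above background.

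By gene list, 25 of 31 naive pluripotency genes differed among the lines, and 26 adjusted over the list alone. They were lower in iPS1 than in iPS4 by a median of -0.371 (camera adjusted p = 9.58e-12) and than in iPS5 by -0.424 (4.04e-09). Fibroblast genes were lower in iPS1 and iPS4 than in iPS5, by medians of -0.485 (9.31e-12) and -0.335 (4.99e-11), and 32 of 37 differed (33 adjusted over the list alone). Interferon response genes were higher in iPS1 than in iPS4 by 0.334 (1.04e-07) and than in iPS5 by 0.293 (1.38e-06), with 20 of 27 differing (21 adjusted over the list alone). The immunoproteasome gene Psmb8 was at 1.91, 0.20 and -0.10 in iPS1, iPS4 and iPS5, Oasl2 at 2.53, 1.19 and 0.73, Gbp2 at 1.43, -0.03 and -0.14 and Isg15 at 1.43, 0.15 and 0.23. Cholesterol synthesis genes were higher in iPS1 than in iPS4 by 0.321 (4.04e-09) and than in iPS5 by 0.402 (1.04e-07), as Fdps shows at -0.22, -1.01 and -1.25. Because the arrays of iPS5 were dim, lists were set beside other genes. Sets of other genes matched on intensity and on the change in iPS1 and iPS4, a comparison chosen after the result was seen, had medians of 0.0479 to 0.235 in iPS5 (central 95% of 1000 sets) against 0.111 for the interferon list. The genes of a set were drawn independently. Such ranges are too narrow for lists whose genes move together, so a list outside its range need not differ beyond the dimness of the arrays. Outside their ranges lay 11 of 25 lists: fibroblast genes at -0.137, just above theirs (-0.298 to -0.151), naive pluripotency at 0.268 (-0.136 to 0.0604), the 4 factors at 0.776 (-0.203 to 0.161), primed epiblast at -0.154 (-0.019 to 0.175), primitive endoderm at 0.157 (-0.0897 to 0.00585), germ line at -0.153 (-0.117 to -0.0154), p53 targets at 0.0563 (-0.11 to 0.0421), glycolysis at -0.738 (-0.391 to -0.138), oxidative phosphorylation at 0.0242 (-0.179 to 0.00975), cholesterol synthesis at -0.433 (-0.256 to -0.0489) and the epithelial and mesenchymal transition at -0.105 (-0.093 to 0.0277). No list passed between any 2 lines with an estimated correlation, the lowest adjusted p being 0.337. That fit leaves few residual degrees of freedom, so a miss does not show that the lines were alike.

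Primitive streak and mesoderm genes were higher in iPS1 than in iPS4 by a median of 0.169 (camera adjusted p = 0.00011) and than in iPS5 by 0.263 (8.82e-05), and 9 of 20 differed among the lines (10 adjusted over the list alone). Primed epiblast genes were higher in iPS1 by 0.32 (0.000293) and 0.521 (0.000271), and 14 of 18 differed (15 adjusted over the list alone). Otx2 was at 0.28, -0.92 and -1.25 in iPS1, iPS4 and iPS5, while Lefty2 had the opposite order at 0.22, 0.86 and 1.45. Germ line genes were lower in iPS4 than in iPS1, with a median of 0.312 for iPS1 over iPS4 (2.03e-07), and 18 of 28 differed (20 adjusted over the list alone). Genes of the 2-cell-like state were higher in iPS1 than in iPS4 by 0.543 (8.59e-06), with 6 of 11 differing (9 adjusted over the list alone). These values also miss the threshold with an estimated correlation (0.337 or more).

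Over all probes the F test among lines called 8241 (4605 genes), of which 384 lay beyond 2-fold. Between iPS1 and iPS4 limma called 3743 probes (2377 higher in iPS1, 1366 lower), between iPS1 and iPS5 7540 (4285 and 3255), and between iPS4 and iPS5 4436 (2211 and 2225). These calls depended on the offset of the background correction: with offset 0 limma called 0 probes in the F test (8821 at an unadjusted p under 0.05), and the named line differences had adjusted p of 0.065 to 0.156. The F count was 585 with plain background subtraction, 640 with median centring and 1494 without a dye term. Subtraction ended the calls of Gbx2, Ntn1 and Ipp, median centring those of Apoe and Pigyl, and fits without a dye term those of Ipp and Pigyl, while scaling the arrays turned the line difference of Ipp around (-0.519 against 1.03). Leaving out an array of iPS1 (3374 and 3475 calls) or of iPS4 (5237 and 4947) lowered the F count by over 1.5 times. Between iPS1 and iPS4 the count was 641 to 1168 without an array of these lines and 7739 without either array of iPS5. Between iPS1 and iPS5 it was 2384 and 3166 without an array of iPS1, and between iPS4 and iPS5 it was 617 and 1201 without an array of iPS4, 2685 without either of iPS1 and 6964 without iPS5 replicate 1. Of the 30 genes named by line difference Ipp lost its call without iPS4 replicate 1 (0.0619).

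Grouped by chromosome, an arrangement chosen after the values had been seen, genes of chromosome 8 were lower in all 3 lines. The median log2 ratio of its 596 genes above background in both channels on all arrays was -0.10 (-0.103 in iPS1, -0.112 in iPS4 and -0.0555 in iPS5), and 69.6% of them lay below 0. The medians of the other 19 chromosomes measured, X included, ran from -0.0347 for chromosome 12 to 0.0275 for chromosome 18. The median of chromosome 8 was below 0 on 6 of 6 arrays, as was that of chromosome 12. Of its 596 genes, limma called 107 lower and 20 higher in the mean of the lines.

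**Figure D5:**
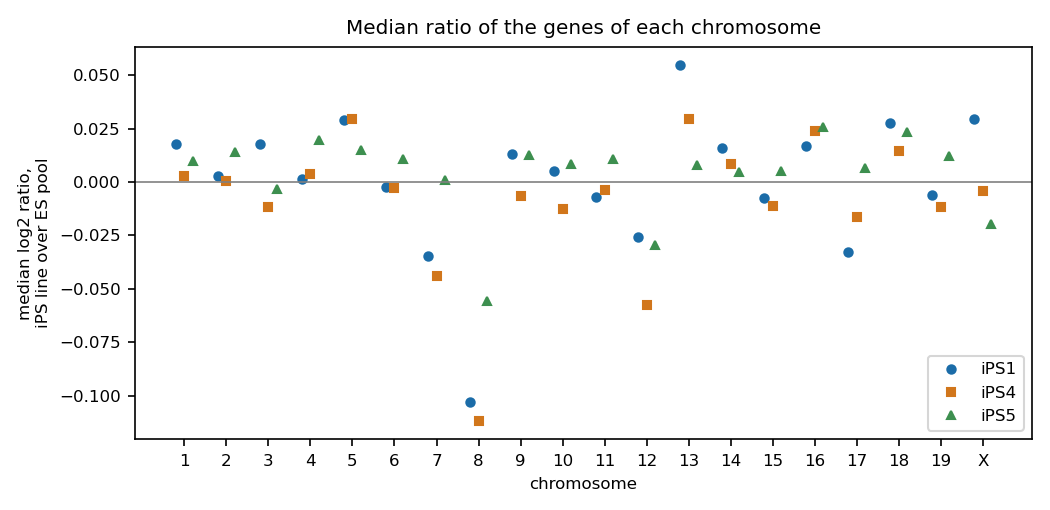
Median log2 ratio to the ES pool (vertical axis) of the genes of each chromosome (horizontal axis), with 1 symbol per line. Chromosome 8 lies lowest in each line, at -0.103, -0.112 and -0.0555.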

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

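The test of dim arrays was chosen only after the line differences had been seen; that of Wnt target genes was set before its list was measured. The results here are differences between lines: named genes whose gap between 2 lines passed a limma treat test of more than 2-fold, 35 of 218 named genes tested and 58 genes in all, and the counts of probes that differed. The gaps are given on the log2 scale, highest line minus lowest.

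Genes of the X-linked Xlr cluster and others were higher in iPS1 than in iPS4. The gap was 4.29 for Xlr4b, 3.83 for Eif2s3y, 3.74 for Xlr5c, 3.37 for Xlr4c, 3.35 for Xlr3c, 2.65 for Xlr5e-ps and 2.07 for Pttg1. It was 3.49 for Meg3, 2.69 for Zscan4c, 2.61 for Zscan4f and 2.04 for Dazl. Xlr4c and Xlr5e-ps were above background on 1 of the 2 iPS4 arrays. Kdm5d, also Y-linked, stood near 0 in iPS1 and iPS4, and whether the Eif2s3y or the Kdm5d probe measures its own gene is unsure.

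Genes higher in iPS5 than in iPS4 were Srgn (3.36), Cubn (2.63), Grb10 (2.03) and Fos (1.75). Those higher in iPS5 than in iPS1 were Coil (2.21), Klf5 (2.08), Tbx3 (2.01), Aard (1.96), Nr0b1 (1.9), Lama1 (1.84), Apoe (1.83) and Klf4 (1.59). Slc39a8 was higher in iPS4 than in iPS5, by 2.23.

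Genes higher in iPS1 than in iPS5 were T (3.08), Sp5 (2.8), Ppp4r4 (2.53), Fgf5 (2.44), Gsc (2.28), Dppa3 (2.13), Psmb8 (2.02), Oasl2 (1.79), Foxa2 (1.59), Gbp2 (1.57) and Otx2 (1.53). For Gsc the iPS channel was not above background in iPS5, and for Sp5 the ES channel was not above background there, so these gaps depend on the background correction. By count, 8241 probes differed among the lines in limma's F test, 3743 between iPS1 and iPS4, 7540 between iPS1 and iPS5 and 4436 between iPS4 and iPS5.

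T, Gsc, Wnt3, Fgf8, Sp5, Fgf5 and Wnt8a, the 7 genes of the epiblast and primitive streak lists with a mean log2 ratio of at least 1 over iPS1 and iPS4, changed less in iPS5, on whose arrays signals were dim. The streak list as a whole had a median of 0.103 over iPS1 and iPS4, 0.0298 in iPS4 alone and 0.0217 in iPS5, inside the range of matched sets of other genes (-0.00207 to 0.0874). The epiblast list had a median of 0.241 over iPS1 and iPS4, -0.00789 in iPS4 alone and -0.154 in iPS5, below its matched sets (-0.019 to 0.175), but its members went both ways there, 5 higher and 9 lower. Compressed ratios on dim arrays cannot be told apart from a difference between lines. The median ratio of the iPS5 change to that mean was 0.149, against 0.214 to 0.592 in the central 95% of 10000 random sets matched on intensity and size, but Gsc, Wnt3 and Sp5 had a channel not above background in iPS5, and for the other 4 genes the ratio of 0.138 lay inside the range of matched sets (0.128 to 0.721). A general rise of Wnt targets in iPS1 and iPS4 stays open but gained little from a list of such genes as a whole. Of 20 other Wnt target genes, 15 lay above 0 in iPS1, 14 in iPS4 and 13 in iPS5. The share in iPS4, 70%, was short of the 75% set as needed. The median difference from iPS5, 0.0231, was far below the difference also set as needed. Neither value reached the level set for excluding such a rise. By the F test 10 of the 20 genes differed among the lines, in different orders. Axin2 stood at 2.18, 1.61 and 0.608 in iPS1, iPS4 and iPS5, and Tnfrsf19 at 1.07, 0.626 and 0.217. Bmp4 ran the other way at 0.118, 0.751 and 1.59, as did Ccnd1 at -0.0209, 0.117 and 0.379. A difference in clonal origin or in the state of the cultures was not tested.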

How the results depend on the processing

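Counting the ES pool as a sample, detection on all 6 arrays, scaling each array and offset 0 were chosen after seeing the data; the other alternatives were planned. Of the alternative values for counts, lists and named genes, 4041 stayed on the same side of the threshold or within range. Calls were lost by 690 and gained by 182, 86 counts moved by over 1.5 times and 40 values changed sign. Many of these values could not change sign. Quantile normalization keeps every ratio, and settings that alter only the test keep every mean and median, so the tally does not measure how firm the directions are. The cause of a change was not tested, except that fewer arrays, lines or probes were used where stated. Signal over background was lowest on the arrays of iPS5. The median of all probes is held near 0 by the normalization, so its shift says nothing. Quantile normalization of mean intensities changes no ratio and says nothing. A single line's arrays fitted alone with a dye term leave no residual degrees of freedom and were not run, and limiting the F test to the arrays compared is the same fit.

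The 3161 probes that differed from the ES pool became 5546 with plain background subtraction, 4967 with median centring, 1526 with gene means (18295 tested), 5048 with arrays scaled, 4883 with offset 0 and 736 with a 1.5-fold requirement. They became 11427 with 6 arrays as separate samples, 8763 with the line as a random block (correlation 0.528) and 0 with the ES pool as 1 sample (limma, 3766 unadjusted). Leaving out 1 array gave 457 to 5881; leaving out a line gave 0 without iPS1 (limma, 8786 unadjusted), 0 without iPS4 (5960 unadjusted) and 5422 without iPS5. Counts within 1.5 times were 3607 with no background correction, 3731 and 4552 with probes filtered on detection on 3 or on all 6 arrays and 4003 with the authors' values.

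For iPS1 alone (14942) the counts were 9333 with subtraction, 7102 with median centring, 7683 with gene means, 7401 with offset 0, 1977 with 1.5-fold and 8242 without a dye term, and 6684 to 18526 without 1 array. For iPS4 (14939) they were 9947, 7690, 7905, 7475, 2014 and 8418, and 7729 to 18263 without 1 array. For iPS5 (8040) they were 2235 with median centring, 4378 with gene means, 950 with 1.5-fold and 2968 without a dye term, and 6749 to 9454 without 1 array.

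For the F test among lines (8241) the counts were 585 with subtraction, 640 with median centring, 4361 with gene means, 0 with offset 0 (limma, 8821 unadjusted), 1580 with 1.5-fold and 1494 without a dye term, and 3374 to 12344 without 1 array. For iPS1 against iPS4 (3743) they were 32, 265, 1972, 0 (limma, 5358 unadjusted), 587 and 584 in the same order, 2229 with arrays scaled, 7739 with only the arrays of the 2 lines, and 641 to 7739 without 1 array. For iPS1 against iPS5 (7540) they were 1976, 1028, 3989, 1119, 1220 and 1933, and 2384 to 9383 without 1 array. For iPS4 against iPS5 (4436) they were 17, 146, 2413, 0 (limma, 7117 unadjusted), 520 and 250, with 2925 when scaled, 2685 with only the arrays of the 2 lines, and 617 to 6964 without 1 array. The dye effect (7631) fell to 0 with offset 0 (limma, 11506 unadjusted), and the 247 probes beyond 2-fold became 807.

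Of 8 lists past the threshold, 0 passed with an estimated correlation in camera (0 unadjusted) and 0 with fry (7 of 25 lists unadjusted), and 1 also had a median of 1.5-fold; other settings gave 7 to 11. List medians that changed sign belonged to lists not past the threshold. Leaving out a line moved the naive list from -0.0868 (without iPS5) to 0.232, the 4 factors from -0.106 (without iPS5) to 0.579, primitive endoderm from -0.0976 (without iPS5) to 0.0567, the 2-cell-like state from -0.2 to 0.0125 (without iPS4), p53 targets from -0.0458 to 0.0271 (without iPS4), LIF-STAT3 and FGF-ERK feedback from -0.0154 (without iPS5) to 0.0448 and the sex-linked list from -0.0356 to 0.00255 (without iPS5). Endothelial genes moved from -0.002 to 0.00727 (without iPS4) and were at 0.00599 without iPS5. With gene means primitive endoderm was at -0.0188, neural at 0.0132 and endothelial at 0.0146, and with all probes they were at -0.00669, 0.019 and 0.00419. With arrays scaled neural was at 0.00189 and p53 targets at 0.00459. P53 targets were at 0.00797 with subtraction and 0.0171 with offset 0. Endothelial genes were at 0.00285 with no correction, 0.00544 with median centring and 0.00712 with detected probes, and LIF-STAT3 and FGF-ERK feedback was at -0.00195 with median centring.

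Gene means that changed sign were of genes not called. Leaving out an array or a line moved Pou5f1 from -0.138 (without iPS5) to 0.45, Klf4 from -0.0868 (without iPS5) to 0.708, Taf5 from -0.085 to 0.00457 (without iPS5), Sox2 from -0.2 to 0.00294 (without iPS1) and Esrrb from -0.298 to 0.285 (without iPS1). With gene means Taf10 was at 0.0659, Zfy1 at -0.0328 and Esrrb at 0.000736. Esrrb was also at 0.00801 with arrays scaled, 0.00474 without iPS4 replicate 1 and 0.011 without iPS5 replicate 2. Kdm5d moved from -0.244 to 0.0189 (without iPS5 replicate 1), and Tal1 from -0.0535 (without iPS4 replicate 2; -0.0527 without iPS1 replicate 2) to 0.315. Among lines, the difference of Ipp turned from 1.03 to -0.519 with arrays scaled, that of Taf7l from 0.487 to -0.174 with offset 0, and that of Flt1, not called, from 0.203 to -0.18 with gene means.

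Of 125 named genes tested against the ES pool 80 were called. Of these 80, calls were lost by 48 without iPS5 replicate 1, 26 without iPS4 replicate 1, 12 without iPS5, 12 with gene means, 11 without iPS1 replicate 2 and 9 with arrays scaled, and by all 80 without iPS1, without iPS4 or with the ES pool as 1 sample. Of 117 genes tested among lines 114 were called, and 113 lost the call with offset 0, 52 with median centring, 47 with subtraction and 32 without a dye term.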

Other observations

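The chromosome scan and the tests of a few strong genes, of dye and intensity, and of fibroblast expression kept from donor cells were chosen only after the result was seen, as were the lists of ATF4 targets and hypoxia genes; the tests of an extra chromosome copy and of feeder cells were set before their values were computed.

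Targets of ATF4, the transcription factor of the amino acid and integrated stress response, were lower in the iPS lines. Of 23 measured, 17 were called lower and 20 lay below 0, with a median of -0.85 on the log2 scale. The list was written after Chac1, Asns and Nupr1 had been seen, so its camera p of 5.78e-12 is no independent evidence, and with an estimated correlation p was 0.0871. Among its members Psat1 stood at -1.28, Ddit3 at -1.27, Sars at -1.05, Trib3 at -1.04 and Mthfd2 at -0.99, while Sesn2 at 0.06, Wars at 0.06 and Cth at 0.38 lay above 0. Chac1, Asns, Ddit3, Trib3 and Sesn2 are also on the stress response list.

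Genes induced by hypoxia were lower as well. Of 22 measured, 13 were called lower and 20 lay below 0, with a median of -0.80 (camera p = 2.81e-10, 0.0742 with an estimated correlation; the list was written after Bnip3 and the glycolysis genes had been seen). Adm stood at -1.65, Ero1a at -1.57, Bhlhe40 at -1.29, Gbe1 at -1.24 and Ndrg1 at -1.06. Ddit4 was at -0.99, -2.04 and -2.65 in iPS1, iPS4 and iPS5. Car9 at 0.12 and Pfkfb4 at 0.18 lay above 0.

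Of the other sex-linked genes beside Eif2s3y, Kdm5d stood at -0.04, -0.06 and -0.23 in iPS1, iPS4 and iPS5 (F test adjusted p = 0.766), Uty at -0.01 and 0.04 in iPS1 and iPS4 (0.163) and Xist at 0.22 and 0.39 (0.0112). In iPS5 Uty was not above background and at least 1.22-fold lower than the ES pool, and Xist was not above background in the ES channel. The authors' table held 3455 reporters with a deposited p-value under 0.05, of which 1657 were higher and 1798 lower in iPS cells, and its ratios correlated across probes with those computed here with r = 0.995.

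Genes of chromosome 8 were lower in all 3 lines, with a median of -0.10, when 20 chromosomes were looked at. A few strongly lower genes are argued against, since 69.6% of its genes lay below 0, against 49.8% of 10163 genes on other autosomes. A dye bias is argued against as well, since the chromosome's median was below 0 on 6 of 6 arrays, which held both dye orientations. The lowest median of 10000 sets of other genes matched on intensity was -0.0327. The genes of a set were drawn independently, so this range is too narrow for genes that move together. Chromosome 12, at -0.0347, also lay below it. An intensity bias is therefore not excluded by these sets. An extra copy of chromosome 8 in part of the ES pool is a candidate explanation that the values do not decide. The medians of 4 segments with equal numbers of genes along the chromosome all lay below 0, at -0.0734, -0.116, -0.116 and -0.0672. Both quartiles were lower than those of other autosomes (-0.278 and 0.0273 against -0.124 and 0.147). These values place the shift along the whole chromosome, but any chromosome-wide shift would give them, whatever its cause. The size depended on the genes chosen, with -0.143 over 363 brighter genes, and a lower dose in the iPS lines or their donor cells, which the same pool cannot separate, was not tested.

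Fibroblast genes were lower in the iPS lines than in the ES pool, with a median of -0.38. Expression kept from the donor fibroblasts cannot be told apart from its absence: 10.8% of the list lay above 0, but that share restates the pattern, and fewer feeder cells would hide kept expression. Fewer feeder fibroblasts in the iPS RNA may account for the shift but cannot be told apart from other differences. In a second list of 38 fibroblast genes, 73.7% lay below 0, short of the 75% set as needed. Its median of -0.0612, with 1 gene called lower, fell well short of the shift also set as needed. The second list thus did not share the size of the first list's shift. A biological difference between iPS and ES cells in these genes was not tested.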
